A study of Homo sapiens with 36 samples.

How the data were processed

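Gene expression was measured in 36 kidney needle biopsies fixed in formalin and embedded in paraffin, each on its own Affymetrix array. The labels put 7 biopsies in a control group (label "normal"), 6 in NAFLD, 5 in NASH, 6 in ALD, 6 in HCV and 6 in ALD/HCV. These are the usual abbreviations of liver diseases, which the labels do not spell out: non-alcoholic fatty liver disease, non-alcoholic steatohepatitis, alcohol-related liver disease and hepatitis C virus infection. From each biopsy 10 ng of total RNA was labelled with the GeneChip WT Pico kit. Each biopsy came from a different patient, so the errors and p of single genes and of list means reflect the spread between biopsies. Arrays are numbered within a group only to name them.

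The deposited values are log2 expression values per transcript cluster. The submitters' processing notes name Affymetrix Expression Console. The summary algorithm, the normalization between arrays and the genome build are not given in the sources used here, and the log2 scale was read from the values, which ran from 0.56 to 12.67. Array medians differed, from 2.91 to 3.51, and no further normalization was applied in the analyses reported first. Of 17959 rows, 16891 named 1 gene symbol, 414 named several and 654 named none. Symbols were compared with a gene table by Entrez identifier, which matched 16272 rows and renamed 0. XIST, TSIX and genes of the Y chromosome (43 rows) were left out, and where a gene had several rows (1 gene) the row of the higher mean was kept, which left 16847 genes. No filter on low values was used. As a guide to background, the 350 olfactory receptor genes had a median of 1.75 and a 95th percentile of 3.51 on the log2 scale, and 56.3% of genes had a mean below that percentile.

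Differences were tested with limma 3.58.1 in R 4.3.3, with 6 group means fitted over the 36 arrays, 30 residual degrees of freedom and moderated variances. The comparisons were 11 contrasts: the unweighted mean of the 5 disease groups against control, each disease against control, NASH against NAFLD, ALD/HCV against ALD, ALD/HCV against HCV, NAFLD and NASH against the other diseases, and the interaction of ALD with HCV. An F test asked for any difference among the 5 disease groups. P values were 2-sided, adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. An exact Wilcoxon test per gene, by enumeration, was run beside limma for contrasts of a single group with another. "Arrays in direction" counts the arrays of the disease that lie on the stated side of the mean of the group it is compared with.

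Gene lists were fixed before the data were examined: 37 lists (17 of cell type markers, 18 of pathways and 2 on sample quality) with 523 distinct genes, of which 462 were measured, 6 to 20 per list. Each list was tested with camera of limma with a preset correlation of 0.01, adjusted over the 37 lists of a contrast, then with the correlation estimated from the data, and with fry of limma. Camera compares the genes of a list with the other genes. With the preset correlation it takes them as nearly independent, so that p does not measure the spread between biopsies. Members of a list were also adjusted over the list alone. List tests had been planned for liver disease and each disease against control and for NASH against NAFLD; those in the other 4 contrasts were added after the data were seen. For each list, the mean over its genes (centred per gene) was taken per array and compared between each disease and control by an exact 2-sided permutation test, 185 tests in all. For a group of 6 against 7 the smallest p such a test can give is 0.000583, and a single list at that value would have an adjusted p of 0.108.

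The rule for named genes was fixed before the data were examined. It took, for liver disease against control, up to 10 rises and 10 falls that passed, and for other contrasts up to 5 of each. Where fewer passed, it took the genes of the smallest p up to 5. It added up to 4 members of each list by their p in liver disease against control. Olfactory receptor, histone, immunoglobulin segment and small RNA genes stayed in the tests. Where olfactory receptor genes, which set the background guide, ranked among the smallest p, they are given as such and the next genes were named too. Of them, 2 are also given where an array lay apart. Members that passed over a list alone were named in addition, after their values were seen. So were other members given as examples of a list in single contrasts, whether or not they passed.

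The titles of 5 arrays (control 4 and 5, NAFLD 2, 5 and 6) end in a file number above 1000, the others in 1 to 46. What these numbers stand for is not given in the sources used here, so they were treated as a possible batch. Other settings were tried: 19 chosen before the data were examined covered normalization, filters, the variance model, the Wilcoxon test, array weights, the file numbers, covariates for the share of cortex and medulla, the list tests and leaving out each array in turn. A further 3 were chosen after seeing the data: without control 5, without the 3 arrays that correlate least with the others, and the array's median as a covariate. The tests were tried on simulated data with 200 changed genes among 16847 that varied independently: limma recovered 88% of changes of 1 log2 unit in liver disease against control and 48% in NASH against NAFLD. Of changes of 0.5, the size of many differences named, it recovered 32% in liver disease, 10% to 18% in each disease against control and 12% in NASH against NAFLD. Correlation between genes was not simulated. The 200 genes were changed at once, by 0.5 to 2 log2 units, and the complement list by 0.5 besides. Many true changes ease the adjusted threshold, so these percentages do not hold where few genes change. That 0 genes passed therefore does not rule out changes of 1 unit. The number of arrays limits the precision of every difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Sex-linked genes and personal details were left out of every table, and signal from raw array images was not analysed here.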

Results

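Global RNA profiles were recorded from needle biopsies of kidney, taken in 5 chronic liver diseases and from controls, to raise hypotheses on how the liver diseases affect the kidney. The 36 arrays comprised 7 control, 6 NAFLD, 5 NASH, 6 ALD, 6 HCV and 6 ALD/HCV biopsies, and 16847 genes were compared. The mean array median was 3.27 (SD 0.09, n = 7) on the log2 scale in control, 3.22 (SD 0.06, n = 6) in NAFLD and 3.29 (SD 0.14, n = 5) in NASH. It was 3.19 (SD 0.18, n = 6) in ALD, 3.31 (SD 0.17, n = 6) in HCV and 3.21 (SD 0.12, n = 6) in ALD/HCV. The first principal component held 27.6% of the variance. Control 5 correlated least with the other arrays (median r = 0.783), followed by ALD 3 (0.863) and ALD 6 (0.889).

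**Figure D1:**
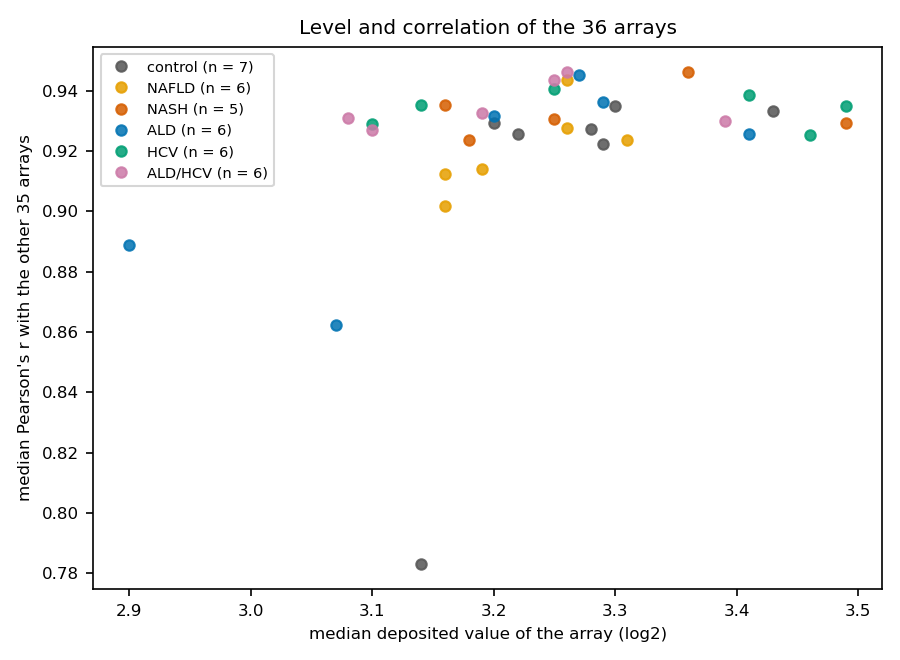
Median log2 value of each array (x axis) against its median Pearson correlation with each other array (y axis), coloured by group. Control 5 lies lowest, at a correlation of 0.783, and ALD 3 next, at 0.863.

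The contrast of liver disease with control asked what the kidneys of the 5 disease groups had in common. A2M, which encodes the secreted protease inhibitor alpha-2-macroglobulin, had the largest difference among the genes of smallest p. Its mean was 5.11 (SD 1.12, n = 7) in control, 5.41 (SD 0.86, n = 6) in NAFLD and 7.63 (SD 0.55, n = 5) in NASH. It was 6.75 (SD 1.28, n = 6) in ALD, 7.07 (SD 0.88, n = 6) in HCV and 7.04 (SD 0.51, n = 6) in ALD/HCV. FAM184B averaged 4.15 (SD 0.25, n = 7) in control and between 3.52 and 3.73 in the diseases. These disease means lay close to the background guide of 3.51, so the size of its fall is uncertain. AGR2, a protein disulfide isomerase of the endoplasmic reticulum, differed by 1.28 (SE 0.32). Its mean was 2.68 (SD 0.80) in control and 3.05 (SD 0.67) in NAFLD, both below the background guide of 3.51, so the sizes of its differences from control are uncertain. Markers of macrophages, antigen presentation, complement, oxidative phosphorylation and ribosomal proteins rose as lists, and cell division genes fell, by camera with a preset correlation. With an estimated correlation none of these 6 passed (adjusted p from 0.745 to 0.889).

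By limma, 0 genes passed in liver disease against control after adjustment over all genes, and 1280 had an unadjusted p under 0.05 (402 higher, 878 lower). The median over all genes was -0.03, and with array medians equalised it was -0.01, with 787 higher and 614 lower. The balance of higher and lower genes thus depended on the scaling of the arrays, here and in the contrasts below, and is not read as a result. FAM184B came closest, with a difference of -0.52 (SE 0.10, adjusted p = 0.105, lower in 29 of 29 disease arrays). A2M differed by 1.67 (SE 0.36, adjusted p = 0.383, higher in 25 of 29). AGR2 had an adjusted p of 0.554 (higher in 25 of 29). So had SLC50A1, a sugar transporter, at -0.62 (SE 0.15, lower in 29 of 29), and REDIC1 at -0.48 (SE 0.12, lower in 27 of 29). SLC50A1 and REDIC1 lay below the background guide. The olfactory receptor gene OR51T1, also below it, ranked among the genes of smallest p (-0.48, SE 0.12, limma adjusted p = 0.554). With the array median as a covariate, an alternative chosen after seeing the data, 6 genes passed: A2M (1.79, adjusted p = 1.25e-05), FAM184B, AGR2, IFI16, HLA-DMA and STK10. Over all settings other than leaving out an array, the adjusted p of A2M ran from 1.25e-05 to 0.999 and that of FAM184B from 0.0414 to 0.493.

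The macrophage and monocyte list rose in liver disease, with 12 of 12 measured genes higher and a median difference of 0.25 on the log2 scale (camera, adjusted p = 9.9e-05, and adjusted p = 0.745 with an estimated correlation). CD163, a scavenger receptor for haemoglobin on macrophages, differed by 1.33 (SE 0.45), C1QC, a chain of complement C1q, by 0.49 (SE 0.18) and MS4A7 by 0.55 (SE 0.24), which were the 3 members at an unadjusted p under 0.05. Complement genes rose with a median of 0.16 and 12 of 16 higher (adjusted p = 0.0166, and adjusted p = 0.745 with an estimated correlation). C7 differed by 0.70 (SE 0.24), C1S by 1.07 (SE 0.38) and the complement regulator CD55 by 0.75 (SE 0.33). Antigen presentation genes rose with a median of 0.19 and 14 of 17 higher (adjusted p = 0.022, and adjusted p = 0.889 with an estimated correlation), with HLA-DMA at 0.88 (SE 0.35) and CD74 at 0.55 (SE 0.32). Cell division genes fell, with 15 of 15 lower and a median of -0.17 (adjusted p = 0.0215, and adjusted p = 0.745 with an estimated correlation). BIRC5 differed by -0.49 (SE 0.16) and the proliferation marker MKI67 by -0.39 (SE 0.15). Oxidative phosphorylation genes rose with a median of 0.18 and 10 of 14 higher (adjusted p = 0.0279, and adjusted p = 0.889 with an estimated correlation), NDUFV1 at 0.38 (SE 0.17). Ribosomal protein genes, a list on sample quality, rose with a median of 0.75 and 14 of 14 higher (adjusted p = 5.12e-09, and adjusted p = 0.745 with an estimated correlation). RPS23 differed by 1.45 (SE 0.54) and RPS18 by 0.87 (SE 0.32). In these 6 lists 0 members passed over all genes and 0 adjusted over the list alone. The oxidative phosphorylation call was lost without control 5 (median 0.01, adjusted p = 0.834) or ALD 5 (adjusted p = 0.054). Other calls were lost as follows: cell division without control 1 (0.112) and control 4 (0.127), antigen presentation without control 3 (0.0564) and control 4 (0.0792), and complement without control 3 (0.0687). Without the 5 arrays numbered above 1000 only the macrophage and ribosomal calls stood among these 6, with adjusted p of 0.156 for complement and antigen presentation, 0.216 for cell division and 0.69 for oxidative phosphorylation. Over all settings other than leaving out an array, the adjusted p of the macrophage list ran from 1.27e-05 to 0.745. Not every disease shared its direction, as macrophage markers in NAFLD had a median of -0.12, with 7 of 12 lower.

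**Figure D2:**
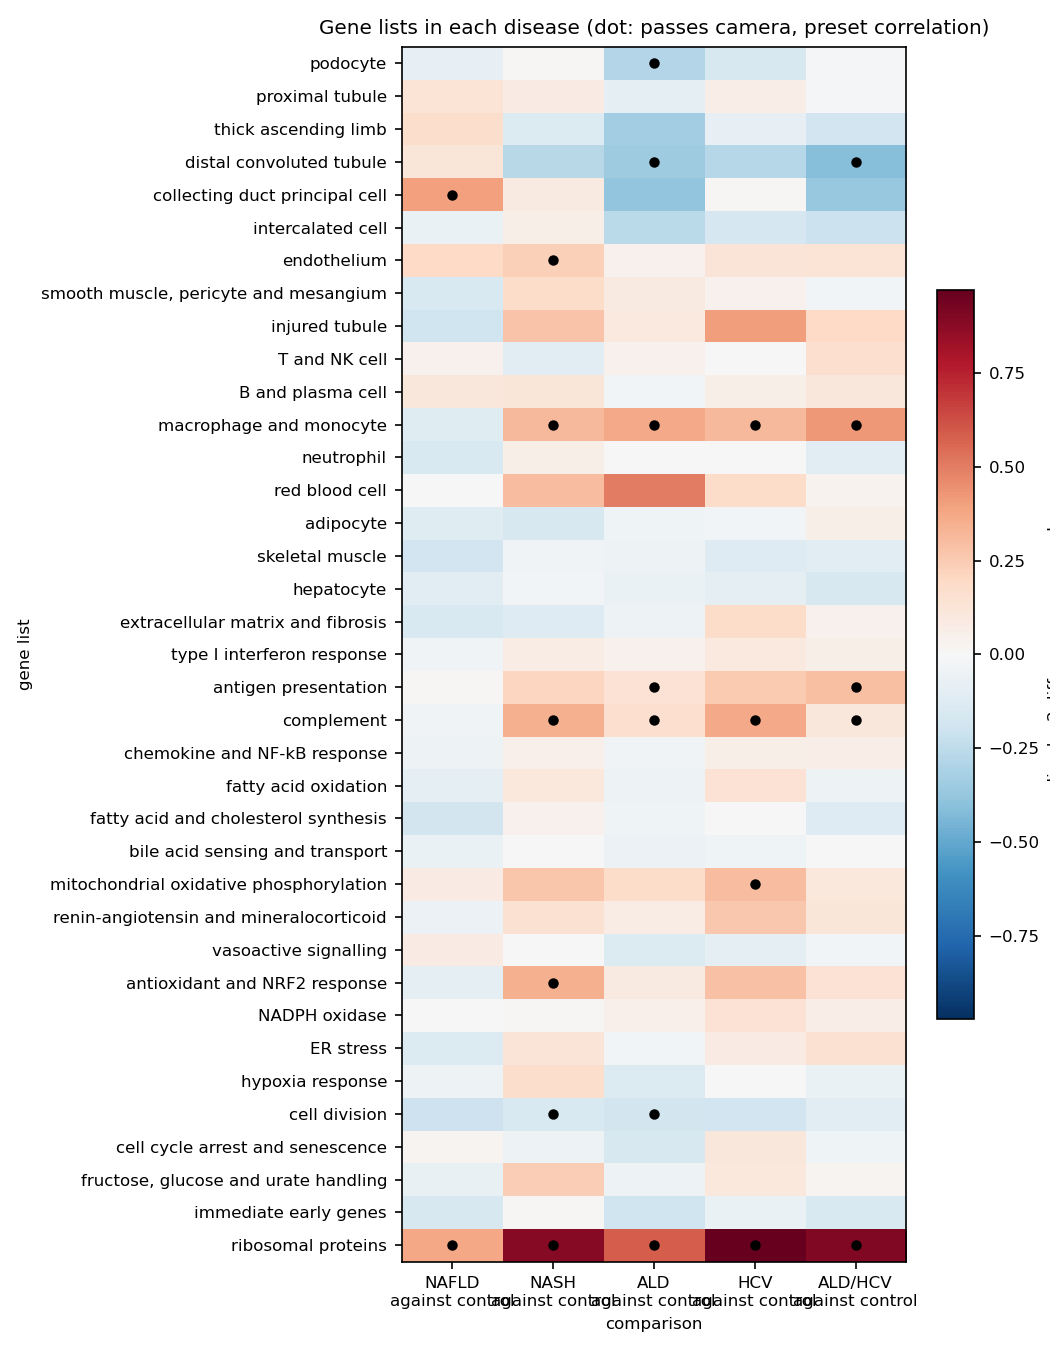
Median log2 difference from control (colour) for 37 gene lists in each of the 5 diseases, with a dot where camera with a preset correlation gave an adjusted p under the threshold of 0.05. The macrophage list has a dot in 4 of the 5 diseases and the ribosomal list in all 5, and with an estimated correlation 0 lists passed.

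None of the 9 lists of kidney cells passed in liver disease. The median difference was -0.10 for podocytes (WT1 -0.44, SE 0.20), 0.05 for the proximal tubule, -0.04 for the thick ascending limb (EGF -0.52, SE 0.20) and -0.33 for the distal convoluted tubule (SLC12A3, the thiazide-sensitive sodium chloride transporter, -0.46, SE 0.34). It was -0.09 for collecting duct principal cells, -0.15 for intercalated cells, 0.12 for endothelium (PECAM1 0.37, SE 0.15), 0.02 for smooth muscle, pericytes and mesangium, and 0.09 for injured tubule (PROM1 0.72, SE 0.39). Camera gave endothelium an adjusted p of 0.0502 and the distal convoluted tubule 0.0813. Leaving out any of control 3 (0.0429), control 6 (0.0169), control 7 (0.0498), NAFLD 2 (0.0452), NAFLD 6 (0.0469), NASH 2 (0.0345), NASH 3 (0.0495), ALD 1 (0.044), ALD 2 (0.0481), ALD 6 (0.029), HCV 1 (0.0355), HCV 4 (0.0431), ALD/HCV 1 (0.0417), ALD/HCV 3 (0.0482) or ALD/HCV 6 (0.0393) brought endothelium under the threshold. The distal convoluted tubule passed without control 1 (0.0387), control 2 (0.0259), control 3 (0.0429), control 5 (0.0376) or NASH 1 (0.0433), and injured tubule passed without control 1 (0.0387).

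Markers of other blood and tissue cells did not pass either. The median was 0.03 for T and NK cells (IL7R 1.02, SE 0.44), 0.05 for B and plasma cells, 0.00 for neutrophils (mean -0.03) and 0.11 for red blood cells. It was -0.01 for adipocytes, -0.10 for skeletal muscle and -0.09 for hepatocytes (FGG -0.31, SE 0.15). JCHAIN, which joins IgA and IgM, differed by 1.75 (SE 0.50, higher in 26 of 29) and passed adjusted over the list alone (adjusted p = 0.0116 in limma, 0.554 over all genes).

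Among the pathway lists that did not pass in liver disease, the median was 0.02 for extracellular matrix and fibrosis (LUM 1.19, SE 0.53), 0.05 for the type I interferon response (MX1 0.67, SE 0.29), 0.05 for chemokines and the NF-kB response, and 0.00 for fatty acid oxidation. It was -0.07 for fatty acid and cholesterol synthesis, -0.06 for bile acid sensing and transport (SLC51B -0.46, SE 0.20), 0.13 for the renin-angiotensin and mineralocorticoid system and -0.06 for vasoactive signalling (NOS3 -0.35, SE 0.13). It was 0.12 for the antioxidant and NRF2 response (SOD1 0.40, SE 0.16), 0.04 for NADPH oxidase, and 0.08 for ER stress. The median was -0.01 for the hypoxia response (mean 0.01), -0.02 for cell cycle arrest and senescence (mean 0.01), 0.04 for fructose, glucose and urate handling, and -0.09 for immediate early genes, the other list on sample quality. Adjusted over the list alone, 5 genes of all lists passed: JCHAIN, the parvalbumin gene PVALB (-0.40, SE 0.13), the muscle myosin MYH2 (-0.32, SE 0.11), the NADPH oxidase organizer NOXO1 (-0.58, SE 0.17) and SDF2L1 (-0.38, SE 0.11). Among the list members named, MS4A7, MKI67, SLC12A3, KLHL3, KCNE1, IL7R, JCHAIN, FGG, LUM, MX1, SLC51B, NOS3, PVALB, NOXO1 and JUND lay below the background guide, as did the control mean of HLA-DMA. Of these, IL7R, JCHAIN, LUM and MX1 averaged above it in some disease groups, such as JCHAIN in ALD (4.03) and ALD/HCV (4.02). TRPM6 of the distal convoluted tubule list and CENPF and BUB1 of the cell division list also lay below the guide, and BIRC5 lay above it. The sizes of the differences of these lists are therefore uncertain, here and in the contrasts below. Matrix genes passed camera without control 1 (median 0.25, adjusted p = 0.00552), the interferon response without control 5 (0.0359) and the antioxidant response without control 2 (0.0178).

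NAFLD was compared with control to describe the kidney in fatty liver. MCM3AP, which encodes an mRNA export factor, differed by -0.87 (SE 0.18, n = 6 and 7), NRIP2 by -0.76 (SE 0.18), FAM184B by -0.56 (SE 0.13) and NFXL1 by 0.63 (SE 0.15). Each lay on the same side of the control mean in 6 of 6 NAFLD arrays. NRIP2 and NFXL1 lay below the background guide. So did the olfactory receptor gene OR8B2, which ranked among the genes of smallest p (0.65, SE 0.15, limma adjusted p = 0.522). Markers of the collecting duct rose, with 7 of 9 genes higher and a median of 0.40 (camera, adjusted p = 0.0482, and adjusted p = 0.998 with an estimated correlation). The water channel gene AQP3 differed by 0.66 (SE 0.34) and HSD11B2 by 0.66 (SE 0.38). Ribosomal protein genes rose, with 12 of 14 higher and a median of 0.37 (adjusted p = 0.0482, and adjusted p = 0.998 with an estimated correlation). A2M differed by 0.30 (exact permutation p = 0.611).

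In NAFLD against control 0 genes passed by limma (MCM3AP adjusted p = 0.405, FAM184B 0.522), 955 had an unadjusted p under 0.05 (245 higher, 710 lower), and the exact Wilcoxon test gave 0 adjusted and 606 unadjusted. The median over all genes was -0.03, and with array medians equalised 441 were higher and 431 lower. The smallest p that the exact Wilcoxon test gave any gene, 0.000583, would have had to be shared by 197 genes for any to pass, so its 0 says little. So small a p needs tied values. Without ties the smallest possible at these group sizes is 0.00117, which 393 genes would have to share. Here and below the smallest p is the one observed, so the numbers of genes needed are lower bounds. In the lists, PVALB (-0.63) and MKI67 (-0.70) passed adjusted over the list alone. MCM3AP passed without NAFLD 3 (adjusted p = 0.0345). The 3 NAFLD arrays numbered above 1000 differed from the 2 such control arrays by 1.43 in the ribosomal list mean and by 0.70 in the collecting duct mean. Among arrays numbered 1 to 46 (3 NAFLD, 5 control) the differences were -0.23 and 0.16. The ribosomal median turned to -0.21 (adjusted p = 0.641) without the arrays numbered above 1000, to -0.13 (0.884) with the file number as a covariate among arrays 1 to 46, and to -0.07 without control 5 (0.967). The ribosomal call was also lost without control 3 (0.0576), control 6 (0.0807), NAFLD 1 (0.163), NAFLD 2 (0.1), NAFLD 4 (0.0836), NAFLD 5 (0.288) or NAFLD 6 (0.0564). The collecting duct call was lost without control 1 (0.357), control 4 (0.166), control 5 (0.243), NAFLD 1 (0.163), NAFLD 2 (0.1), NAFLD 3 (0.227) or NAFLD 5 (0.202).

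In NASH against control, A2M had the largest difference of the genes of smallest p, 2.53 (SE 0.50, n = 5 and 7, higher in 5 of 5). ERRFI1, a feedback inhibitor of the EGF receptor, differed by 1.84 (SE 0.41), the glucocorticoid-induced gene TSC22D3 by 1.03 (SE 0.23), WDR5B by 0.96 (SE 0.22) and FAM184B by -0.63 (SE 0.14), each in 5 of 5 arrays. ERRFI1 and WDR5B lay below the background guide over all arrays, ERRFI1 with a NASH mean of 4.65 above it. Macrophage markers rose, with 12 of 12 higher and a median of 0.32 (camera, adjusted p = 0.000814, and adjusted p = 0.685 with an estimated correlation). CD163 (2.37, SE 0.63) and C1QC (0.92, SE 0.25) passed adjusted over the list alone. Complement (median 0.35, 12 of 16 higher, adjusted p = 0.0138), antioxidant (0.34, 13 of 16 higher, 0.0138), endothelium (0.24, 11 of 12 higher, 0.0307) and ribosomal genes (0.89, 13 of 14 higher, 1.14e-05) rose. Cell division genes fell (-0.15, 14 of 15 lower, 0.0146). Each of these 5 lists had an adjusted p = 0.685 with an estimated correlation.

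Of single genes, 0 passed by limma in NASH against control (A2M adjusted p = 0.225, ERRFI1 and TSC22D3 0.359), 1020 had an unadjusted p under 0.05 (548 higher, 472 lower), and the exact Wilcoxon test gave 0 adjusted and 1080 unadjusted (426 genes would have had to share its smallest p to pass). With array medians equalised 699 were higher and 518 lower. CXCL8, a chemokine for neutrophils, also passed adjusted over the list alone (1.34). A2M passed without control 1 (2.81, adjusted p = 0.0307) and after quantile normalization (2.40, adjusted p = 0.00682), and over all settings other than leaving out an array its adjusted p ran from 3.03e-05 to 0.784. Without NASH 2, 10 lists passed in place of 6. The endothelium call was lost without control 1 (0.0742), control 4 (0.0707), control 5 (0.0586), NASH 1 (0.0561), NASH 4 (0.0838) or NASH 5 (0.0903). The complement call was lost without control 3 (0.0556), NASH 3 (0.0622) or NASH 4 (0.0838). The antioxidant call was lost without NASH 3 (0.245) or NASH 4 (0.0838). The cell division call was lost without control 1 (0.0742) or control 4 (0.0707). Without the arrays numbered above 1000, the endothelium, complement, antioxidant and cell division lists did not pass (adjusted p from 0.137 to 0.207).

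In ALD against control, FOXM1, a transcription factor of the cell cycle, differed by -0.59 (SE 0.13, n = 6 and 7), C11orf96 by -0.75 (SE 0.17), REDIC1 by -0.66 (SE 0.16), SLC17A7 by -0.73 (SE 0.18) and the troponin gene TNNI2 by -0.68 (SE 0.17), each lower in 6 of 6 arrays. TNNI2 alone of these lay above the background guide. Macrophage markers rose (median 0.37, 10 of 12 higher, camera adjusted p = 1.97e-06, and adjusted p = 0.594 with an estimated correlation), with C1QC at 0.68 (SE 0.23) and MS4A7 at 0.81 (SE 0.32). Markers of podocytes fell (-0.29, 9 of 10 lower, adjusted p = 0.0462, CLIC5 -0.89, SE 0.36, and adjusted p = 0.594 with an estimated correlation). So did those of the distal convoluted tubule (-0.34, 6 of 7 lower, adjusted p = 0.0386, CALB1 -1.08, SE 0.50) and cell division genes (-0.18, 11 of 15 lower, adjusted p = 0.0386), each with an adjusted p = 0.594 with an estimated correlation. Complement (0.16, 11 of 16 higher, adjusted p = 0.021, and adjusted p = 0.594 with an estimated correlation) and antigen presentation genes (0.14, 12 of 17 higher, adjusted p = 0.0303, and adjusted p = 0.685 with an estimated correlation) rose. Ribosomal genes rose as well (0.59, 14 of 14 higher, adjusted p = 1.97e-06, and adjusted p = 0.594 with an estimated correlation).

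By limma 0 genes passed in ALD against control (FOXM1 and the other 4, adjusted p = 0.733), 1034 had an unadjusted p under 0.05 (158 higher, 876 lower), and the exact Wilcoxon test gave 0 adjusted and 629 unadjusted (197 genes would have had to share its smallest p to pass). The median over all genes was -0.07, and with array medians equalised it was 0.01, with 451 higher and 406 lower. JCHAIN (2.24), MYH2 (-0.51), BIRC5 (-0.63) and MKI67 (-0.58) passed adjusted over the list alone. The number of passing lists went from 7 to 11 without control 1, to 3 without control 7 or ALD 5 and to 2 without ALD 1. The podocyte call was lost without control 2 (0.16), control 6 (0.198), control 7 (0.101), ALD 1 (0.12), ALD 2 (0.0575), ALD 3 (0.076), ALD 4 (0.0744) or ALD 5 (0.0601). The distal convoluted tubule call was lost without control 6 (0.135), control 7 (0.161), ALD 1 (0.11), ALD 3 (0.112) or ALD 4 (0.055). The cell division call was lost without control 1 (0.114), control 4 (0.11), control 5 (0.0954), control 7 (0.0524), ALD 1 (0.0972), ALD 3 (0.0503) or ALD 5 (0.135). The antigen presentation call was lost without control 5 (0.0602), control 7 (0.0524), ALD 1 (0.0972), ALD 2 (0.0773) or ALD 5 (0.279). The complement call was lost without control 3 (0.0601), control 5 (0.0724), control 7 (0.0514), ALD 1 (0.0901) or ALD 5 (0.0588). Without the arrays numbered above 1000 the cell division (0.307), antigen presentation (0.103) and complement (0.114) lists did not pass, and with the podocyte and collecting duct means as covariates the distal convoluted tubule list did not (0.364).

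In HCV against control, the kinase gene STK35 differed by 0.97 (SE 0.20, n = 6 and 7), A2M by 1.97 (SE 0.48) and AGR2 by 1.69 (SE 0.42). ENPP1, an ectoenzyme that makes pyrophosphate, differed by 0.97 (SE 0.24) and PI15 by -0.59 (SE 0.13). All 5 were on the stated side of control in 6 of 6 arrays, and ENPP1 and PI15 lay below the background guide, as did the control means of STK35 and AGR2. Macrophage markers rose (median 0.32, 12 of 12 higher, camera adjusted p = 0.00104), with lysozyme LYZ at 1.96 (SE 0.76). So did complement (0.37, 13 of 16 higher, adjusted p = 0.0111, C7 1.15, SE 0.32), oxidative phosphorylation (0.30, 13 of 14 higher, adjusted p = 0.0273, COX5B 0.41, SE 0.20) and ribosomal genes (0.97, 14 of 14 higher, adjusted p = 1.22e-06). Each of these 4 lists had an adjusted p = 0.82 with an estimated correlation. C7 and the interferon-induced gene MX1 (1.43) passed adjusted over the list alone, and the interferon list itself did not pass.

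Of single genes, 0 passed by limma in HCV against control (STK35 adjusted p = 0.582, A2M and AGR2 0.685), 1220 had an unadjusted p under 0.05 (672 higher, 548 lower), and the exact Wilcoxon test gave 0 adjusted and 847 unadjusted (197 genes would have had to share its smallest p to pass). With array medians equalised 807 were higher and 682 lower. List calls went from 4 to 8 without control 1 and to 7 without control 2 or HCV 2. The oxidative phosphorylation call was lost without control 5 (0.17, adjusted p = 0.371) or HCV 4 (0.15, adjusted p = 0.145), and the complement call without HCV 4 (adjusted p = 0.0501). Without the arrays numbered above 1000 the oxidative phosphorylation list did not pass (adjusted p = 0.495).

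In ALD/HCV against control, AGR2 differed by 1.72 (SE 0.42, n = 6 and 7) and A2M by 1.93 (SE 0.48). The transcription factor GATA4 differed by -0.71 (SE 0.17), FAM184B by -0.52 (SE 0.13) and TICAM1, an adaptor of Toll-like receptor signalling, by -0.62 (SE 0.16). All 5 were on the stated side of control in 6 of 6 arrays, and GATA4 and the control mean of AGR2 lay below the background guide. Macrophage markers rose (median 0.42, 12 of 12 higher, camera adjusted p = 1.03e-06), with CD163 at 1.55 (SE 0.60). So did antigen presentation (0.29, 13 of 17 higher, adjusted p = 0.00249, CD74 1.04, SE 0.42, and HLA-DMA 1.14, SE 0.47), complement (0.11, 11 of 16 higher, adjusted p = 0.0304) and ribosomal genes (0.90, 14 of 14 higher, adjusted p = 4.5e-09). Markers of the distal convoluted tubule fell, with 7 of 7 lower (-0.41, adjusted p = 0.0304, KLHL3 -0.41, SE 0.20). KLHL3, SLC12A3, PVALB and TRPM6 of this list lay below the background guide, so the size of the fall is uncertain. Each of the 5 lists had an adjusted p = 0.596 with an estimated correlation.

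By limma 0 genes passed in ALD/HCV against control (AGR2, A2M, GATA4, FAM184B and TICAM1, adjusted p = 0.664), 1135 had an unadjusted p under 0.05 (268 higher, 867 lower), and the exact Wilcoxon test gave 0 adjusted and 907 unadjusted (393 genes would have had to share its smallest p to pass). The median over all genes was -0.06, and with array medians equalised 713 were higher and 438 lower. EGF (-0.94), JCHAIN (2.23), MYH2 (-0.46) and SDF2L1 (-0.55) passed adjusted over the list alone. The number of passing lists went from 5 to 8 without control 1, to 3 without control 4 and to 2 without ALD/HCV 6. The distal convoluted tubule call was lost without control 4 (0.0556), control 6 (0.115), control 7 (0.128), ALD/HCV 4 (0.0613) or ALD/HCV 6 (0.113). The complement call was lost without control 3 (0.11), control 4 (0.0556), control 5 (0.0586), control 7 (0.0723), ALD/HCV 2 (0.0639), ALD/HCV 3 (0.0621), ALD/HCV 5 (0.0503) or ALD/HCV 6 (0.077). The antigen presentation call was lost without ALD/HCV 6 (0.077).

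**Figure D3:**
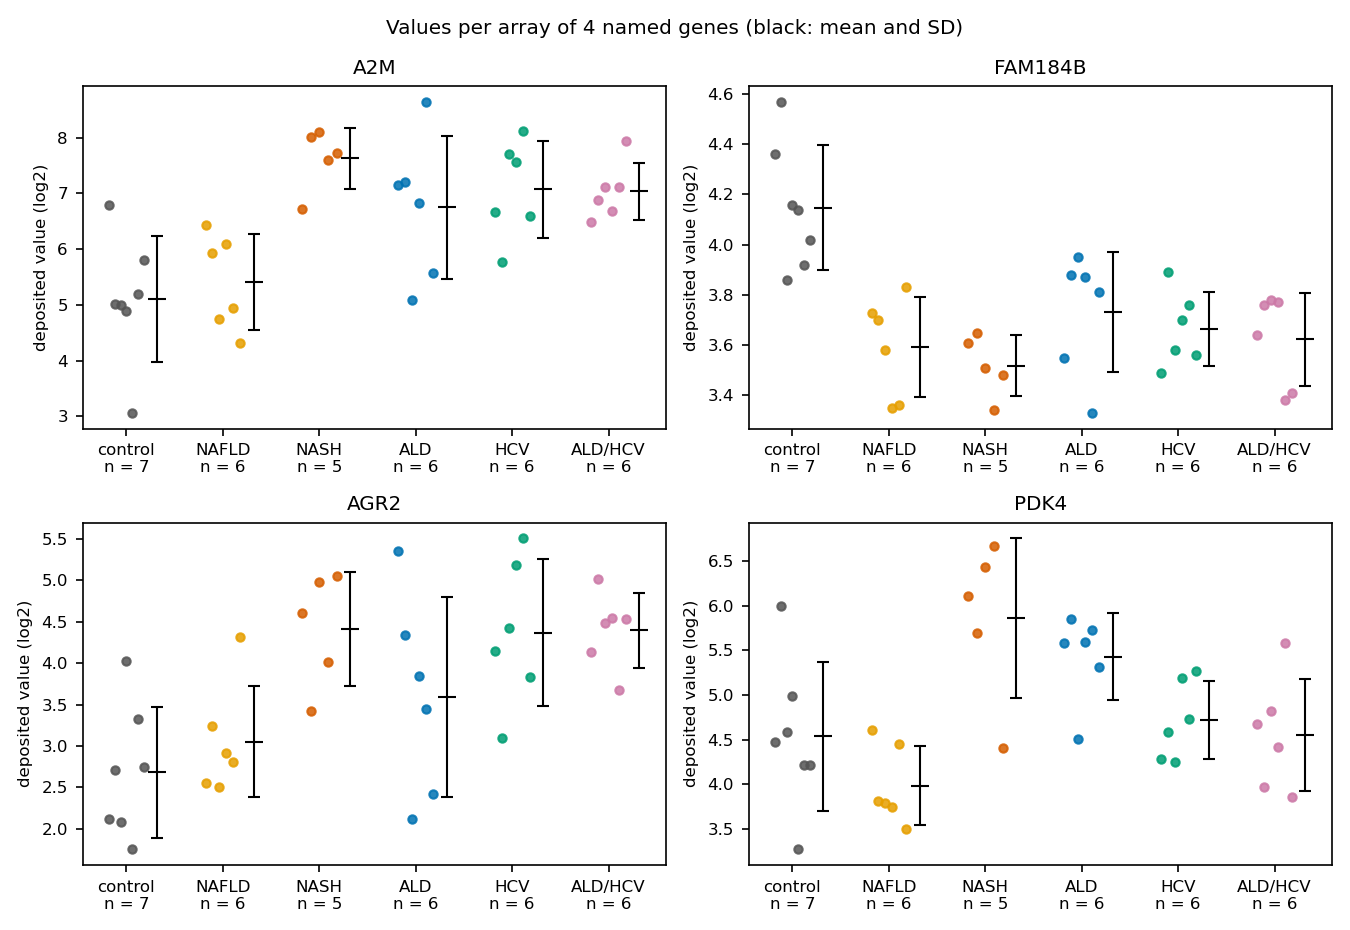
Log2 expression (y axis) of A2M, FAM184B, AGR2 and PDK4 in each array by group (x axis), with the mean and SD of each group. A2M averages 5.11 in control and 7.63 in NASH, and FAM184B lies below the control mean of 4.15 in 29 of 29 disease arrays.

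The 5 diseases share the same 7 control arrays, so their differences from control are not independent of each other. Tested alone, A2M had an exact permutation p of 0.00379 in NASH, 0.0274 in ALD, 0.00699 in HCV and 0.00291 in ALD/HCV. For FAM184B it was 0.00117 in NAFLD, 0.00126 in NASH, 0.00758 in ALD, 0.00291 in HCV and 0.00117 in ALD/HCV. For AGR2 it was 0.383 in NAFLD, 0.00505 in NASH, 0.132 in ALD, 0.00641 in HCV and 0.00233 in ALD/HCV. These p values are not adjusted, and the 3 genes had been picked from 16847 by their p.

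List means per array gave a test that takes the array as the unit. Of 185 exact permutation tests 0 passed after adjustment (smallest adjusted p = 0.815) and 6 had an unadjusted p under 0.05. These were skeletal muscle in NAFLD (-0.17, exact p = 0.00932) and ALD/HCV (-0.17, exact p = 0.0181), and ER stress in NAFLD (-0.23, exact p = 0.0326). The others were cell division in ALD (-0.23, exact p = 0.0443), B and plasma cells in ALD/HCV (0.29, exact p = 0.046) and the distal convoluted tubule in ALD/HCV (-0.44, exact p = 0.046). The macrophage mean differed by 0.60 in ALD/HCV (exact p = 0.0845), 0.58 in HCV (exact p = 0.101) and 0.56 in NASH (exact p = 0.105). It differed by 0.52 in ALD (exact p = 0.155) and by -0.12 in NAFLD (exact p = 0.868). The ribosomal mean differed by 0.82 in ALD/HCV (exact p = 0.0973).

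**Figure D4:**
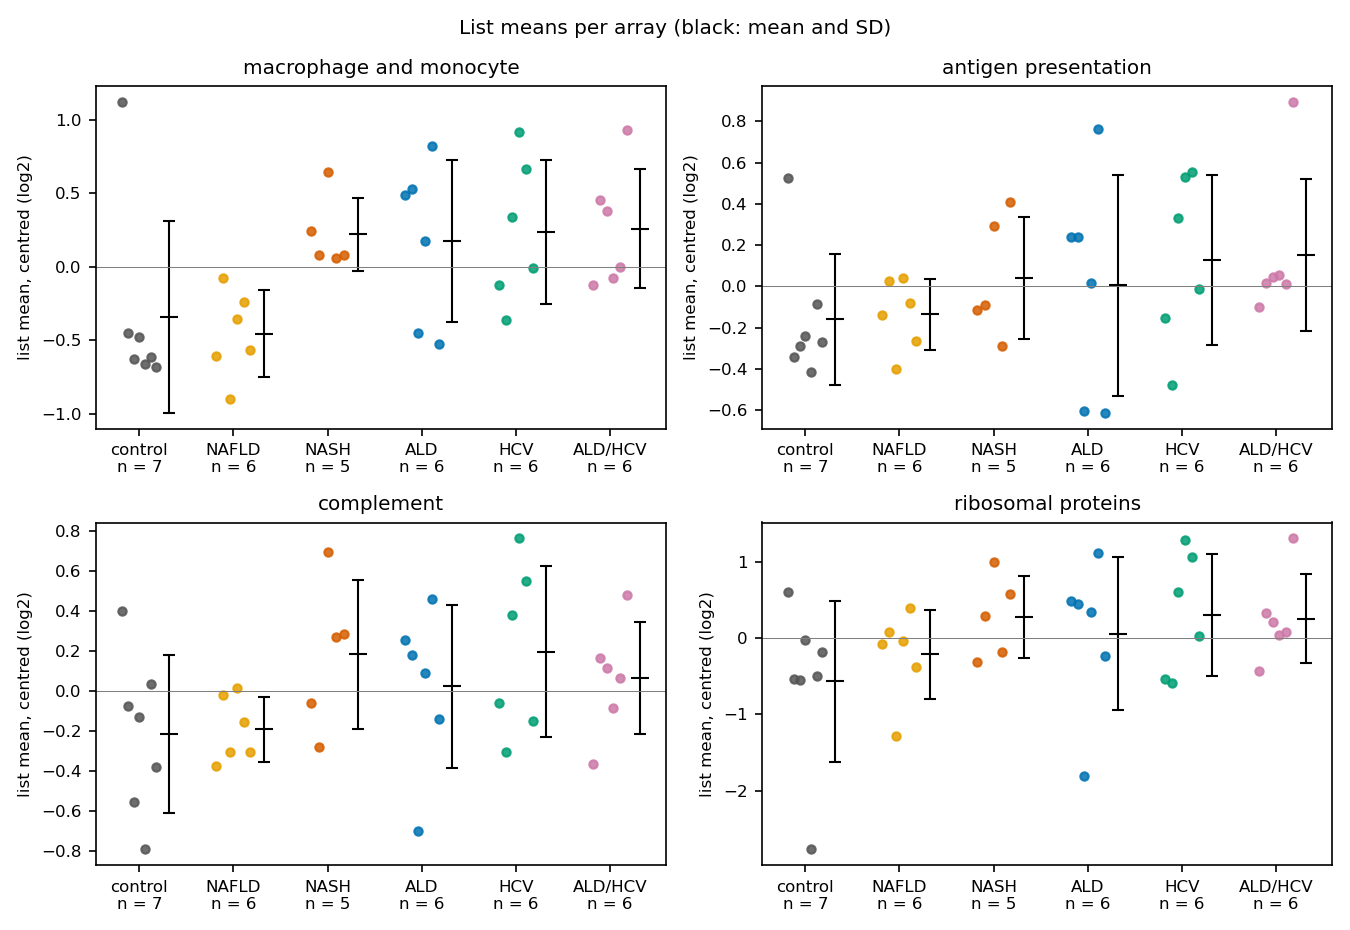
Mean of the genes of 4 lists per array (log2, centred per gene; y axis) by group (x axis), with the mean and SD of each group. The macrophage mean is 0.60 higher in ALD/HCV than in control (exact permutation p = 0.0845), and control 5 is lowest of its group for ribosomal proteins at -2.78.

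NASH was compared with NAFLD to separate steatohepatitis from fatty liver. PDK4, a kinase that slows glucose oxidation, differed by 1.88 (SE 0.37, n = 5 and 6) and C1QC by 1.26 (SE 0.25). The GTPase gene RHOC differed by 1.90 (SE 0.40), ERRFI1 by 1.97 (SE 0.43) and TMEM132E by -0.93 (SE 0.21), each in 5 of 5 NASH arrays. RHOC and ERRFI1 lay below the background guide over all arrays, but above it in NASH (means of 4.42 and 4.65). Their NAFLD means lay below it, as did the NASH mean of TMEM132E. The olfactory receptor genes OR8B2 (-0.76, SE 0.16) and OR2V2 (-0.86, SE 0.19) also ranked among the smallest p, each with a limma adjusted p = 0.132. Macrophage markers were higher in NASH, with 12 of 12 higher and a median of 0.54 (camera, adjusted p = 0.000201, and adjusted p = 0.795 with an estimated correlation). C1QC, CD163 (2.27, SE 0.65) and CD68 (0.72, SE 0.27) passed adjusted over the list alone. ER stress genes (0.34, 13 of 15 higher, adjusted p = 0.0102, the chaperone HSPA5 1.37, SE 0.40, and HERPUD1 0.97, SE 0.32) and chemokine and NF-kB genes (0.30, 14 of 18 higher, adjusted p = 0.0102, CXCL8 1.31, SE 0.42) were higher, each with an adjusted p = 0.795 with an estimated correlation. Antioxidant genes (0.48, 13 of 16 higher, adjusted p = 0.0102, PRDX1 1.02, SE 0.42) and complement genes (0.33, 14 of 16 higher, adjusted p = 0.0252, SERPING1 0.62, SE 0.22) were also higher, each with an adjusted p = 0.795 with an estimated correlation. The 2 lists on sample quality went the same way without passing: ribosomal genes (0.43, 13 of 14 higher, adjusted p = 0.112) and immediate early genes (0.18, 11 of 14 higher, adjusted p = 0.334). All 3 arrays numbered above 1000 in this contrast were NAFLD, so no within-class value exists for that class. With all of them left out, 9 lists passed.

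After adjustment 0 genes passed by limma in NASH against NAFLD (PDK4, C1QC, RHOC and ERRFI1, adjusted p = 0.132, TMEM132E 0.228), 1331 had an unadjusted p under 0.05 (838 of them higher), and the exact Wilcoxon test gave 0 adjusted and 961 unadjusted. Its smallest exact p, 0.00216, would have had to be shared by 730 genes for any to pass, so this 0 says little. The median over all genes was 0.04, and with array medians equalised 656 were higher and 791 lower. Adjusted over the list alone, HSPA5, HERPUD1, ATP6AP2 (1.19), CTSA (1.09) and JUND (0.77) passed besides the 3 macrophage genes. Leaving out NAFLD 1 brought 3 genes under the threshold, with PDK4 at 2.00 and C1QC at 1.40 (adjusted p = 0.0435 for both). It was 1 gene without NASH 2 (ERRFI1, 2.36, adjusted p = 0.0468) and 1 without NASH 5 (PDK4, 2.24, adjusted p = 0.00463). The number of passing lists went from 5 to 8 without NASH 1, to 12 without NASH 2, to 3 without NASH 3 and to 2 without NASH 4. The complement call was lost without NAFLD 1 (0.0761), NASH 3 (0.185) or NASH 4 (0.11). The antioxidant call was lost without NASH 3 (0.237) or NASH 4 (0.0671). The chemokine call was lost without NASH 4 (0.0671).

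ALD/HCV was compared with ALD and with HCV to see what the second disease adds. Against ALD, the genes of smallest p were NAT8L (-0.67, SE 0.18), which makes N-acetylaspartate, SERPINB10 (-0.69, SE 0.19), LRRC57 (-0.58, SE 0.16), REG1A (-0.73, SE 0.21) and SH3PXD2A (-0.57, SE 0.16). Against HCV they were VPS26B (-0.80, SE 0.21), a part of the retromer, TICAM1 (-0.58, SE 0.16), ETAA1 (-0.59, SE 0.17), METTL15 (-1.21, SE 0.34) and URM1 (-0.77, SE 0.22). All 10 were lower in 6 of 6 ALD/HCV arrays, and only SH3PXD2A, TICAM1, ETAA1 and METTL15 lay above the background guide, SH3PXD2A and METTL15 with ALD/HCV means below it. The olfactory receptor gene OR11H6 also ranked among those of smallest p against ALD (-0.51, SE 0.14, limma adjusted p = 0.999). By limma 0 genes passed (adjusted p = 0.999 and 1), with 502 (240 higher, 262 lower) and 500 (89 higher, 411 lower) at an unadjusted p under 0.05. Against HCV the median over all genes was -0.07, and with array medians equalised it was 0.03, with 276 higher and 157 lower; against ALD 277 were then higher and 297 lower. The exact Wilcoxon test gave 0 adjusted in both and 427 and 643 unadjusted (730 genes would have had to share its smallest p to pass). By camera 0 lists passed in either contrast, with 3 and 2 at an unadjusted p under 0.05 and 0 by fry. S100A12 (-0.62) against ALD and the myoglobin gene MB (-0.50) against HCV passed adjusted over the list alone, and without ALD/HCV 4, 1 list passed against ALD.

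NAFLD and NASH, the metabolic diseases, were compared with ALD, HCV and ALD/HCV. The list tests here, for the interaction and between ALD/HCV and its parts were added after the data were seen. Collecting duct markers were higher in the metabolic diseases, with 8 of 9 higher and a median of 0.45 (camera, adjusted p = 5.82e-06, and adjusted p = 0.14 with an estimated correlation). KCNE1 (0.70, SE 0.19), GATA3 (0.46, SE 0.16), HSD11B2 (0.72, SE 0.26), which inactivates cortisol, and the sodium channel subunit SCNN1B (0.43, SE 0.17) passed adjusted over the list alone. Markers of intercalated cells (0.26, 8 of 9 higher, adjusted p = 0.00291, and adjusted p = 0.14 with an estimated correlation) and of the distal convoluted tubule (0.38, 5 of 7 higher, adjusted p = 0.0415, and adjusted p = 0.729 with an estimated correlation) were higher too. The distal convoluted tubule mean was 0.26 in NAFLD and 0.02 in NASH, beside -0.27 in ALD, 0.00 in HCV and -0.24 in ALD/HCV, so NASH lay close to HCV. All 3 disease arrays numbered above 1000 were NAFLD. Macrophage markers were lower (-0.30, 12 of 12 lower, adjusted p = 5.82e-06, and adjusted p = 0.33 with an estimated correlation), with CD14 at -0.52 (SE 0.22). The 2 metabolic groups went apart here: the macrophage list mean was -0.46 in NAFLD and 0.22 in NASH, beside 0.17 in ALD, 0.24 in HCV and 0.26 in ALD/HCV. Injured tubule (-0.30, 12 of 14 lower, adjusted p = 0.00342, HAVCR1 -0.49, SE 0.29) and extracellular matrix (-0.18, 12 of 15 lower, adjusted p = 0.00615, TGFB1 -0.51, SE 0.17) were lower, each with an adjusted p = 0.729 with an estimated correlation. The injured tubule mean was -0.34 in NAFLD and 0.10 in NASH, with 0.04 in ALD, 0.26 in HCV and 0.15 in ALD/HCV. The matrix mean was -0.19 in NAFLD and 0.01 in NASH, with -0.07 in ALD, 0.24 in HCV and 0.13 in ALD/HCV. In both lists NASH lay within the range of the other 3. Antigen presentation (-0.14, 11 of 17 lower, adjusted p = 0.0343) and ER stress genes (-0.08, 13 of 15 lower, adjusted p = 0.0343) were lower, each with an adjusted p = 0.729 with an estimated correlation. The ER stress list mean was -0.24 in NAFLD and 0.14 in NASH, with -0.02 in ALD, 0.10 in HCV and 0.06 in ALD/HCV, so the lower value came from NAFLD and not from NASH. The antigen presentation mean was -0.14 in NAFLD and 0.04 in NASH, within the range of the other 3 (0.01 in ALD, 0.13 in HCV and 0.15 in ALD/HCV). Ribosomal genes were lower as well (-0.18, 12 of 14 lower, adjusted p = 0.0343, and adjusted p = 0.857 with an estimated correlation). Their mean was -0.21 in NAFLD and 0.28 in NASH, beside 0.06 in ALD, 0.31 in HCV and 0.26 in ALD/HCV, so NASH was not low.

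Single genes of smallest p between metabolic and other diseases were the coagulation factor F5 (0.46, SE 0.10, higher in 11 of 11), the antimicrobial peptide gene CAMP (0.40, SE 0.10, 10 of 11), and KRTAP4-2 (0.53, SE 0.14, 10 of 11). The next were ZNF865 (0.62, SE 0.16, 10 of 11) and NIPAL3 (0.49, SE 0.13, 9 of 11), and of these 5 all but NIPAL3 lay below the background guide. By limma 0 passed (adjusted p = 0.983), and 650 had an unadjusted p under 0.05 (455 higher, 195 lower, and 342 and 317 with array medians equalised). MYH2 (0.30), GCLC (0.48) and EDEM1 (-0.50) passed adjusted over the list alone besides the 4 collecting duct genes. The number of passing lists went from 9 to 5 without NAFLD 3, ALD 1, ALD 2, HCV 5 or ALD/HCV 6. By camera with a preset correlation, calls of the collecting duct, intercalated cells, macrophages, injured tubule and matrix survived each left-out array. Those of the distal convoluted tubule, ribosomal proteins, antigen presentation and ER stress were lost without any of NAFLD 3 (0.188, 0.291, 0.0963 and 0.0963), ALD 1 (0.072, 0.072, 0.0681 and 0.0711), ALD 2 (0.0602, 0.0616, 0.0616 and 0.0616), HCV 5 (0.0929, 0.0929, 0.0803 and 0.0803) or ALD/HCV 6 (0.118, 0.118, 0.118 and 0.0851). Some of these were also lost without NAFLD 1, 2, 4, 5 or 6, NASH 1, 2, 3, 4 or 5, ALD 3, 4, 5 or 6, HCV 1, 2 or 4, or ALD/HCV 4 or 5 (adjusted p from 0.0501 to 0.216). With the podocyte and collecting duct means as covariates, which stand for the share of cortex and medulla, 4 lists passed. The collecting duct list could not be called in that setting, as its own mean was a covariate. Among the other calls then lost were those of the intercalated (adjusted p = 0.167), injured tubule (0.229) and matrix (0.0798) lists.

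The interaction asked whether ALD/HCV differed from the sum of ALD and HCV. Podocyte markers had a positive interaction (median 0.36, 8 of 10 higher, camera adjusted p = 0.0213, PODXL 0.86, SE 0.36), as had cell division genes (0.17, 13 of 15 higher, adjusted p = 0.0213, CCNB2 0.88, SE 0.30). Each had an adjusted p = 0.937 with an estimated correlation. Macrophage (-0.36, 12 of 12 lower, adjusted p = 0.0213, C1QC -0.71, SE 0.34), complement (-0.42, 13 of 16 lower, adjusted p = 0.0299, C1R -0.99, SE 0.43) and ribosomal genes (-0.56, 14 of 14 lower, adjusted p = 0.0121, RPL5 -1.16, SE 0.56) had a negative one, each with an adjusted p = 0.937 with an estimated correlation. The contrast adds the control mean, so a control mean below disease groups that are alike gives a negative value by itself. A control mean above them gives a positive value. The ribosomal list mean was -0.56 in control, 0.06 in ALD, 0.31 in HCV and 0.26 in ALD/HCV. The macrophage list mean was -0.34, 0.17, 0.24 and 0.26 in the same groups. The complement list mean was -0.21, 0.025, 0.20 and 0.06 in these groups, and the cell division mean 0.14, -0.09, -0.01 and 0.01. The podocyte mean was 0.11, -0.22, -0.03 and 0.015, so it too was highest in control, with ALD lowest. For none of the 5 lists does the contrast separate an interaction from a control mean that lies apart from the disease groups. Single genes of smallest p were METTL1 (1.22, SE 0.29), STK35 (-1.18, SE 0.29), the bile acid transporter SLC10A1 (0.83, SE 0.21), CRYGD (0.86, SE 0.22) and ALDH3B2 (1.15, SE 0.30), and SLC10A1, CRYGD and ALDH3B2 lay below the background guide. By limma 0 passed (adjusted p = 0.999), 548 had an unadjusted p under 0.05 (308 higher, 240 lower, and 326 and 267 with array medians equalised), and 0 members passed adjusted over the list alone. The number of passing lists went from 5 to 0 without ALD 5, to 1 without control 5, to 2 without ALD 1 or HCV 4 and to 3 without control 6, ALD 2, HCV 5 or ALD/HCV 4. Single calls were also lost without control 1 (cell division, 0.0598), control 2 (podocytes, 0.0723), control 3 (complement, 0.0978), control 7 (complement, 0.0553), ALD 6 (complement, 0.0667), HCV 1 (podocytes, 0.0762), ALD/HCV 1 (complement, 0.0716) and ALD/HCV 5 (podocytes, 0.0547).

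For any difference among the 5 disease groups, the F test of limma passed 0 genes, and 811 had an unadjusted p under 0.05. The olfactory receptor gene OR8B2, below the background guide, had the smallest p (F test, adjusted p = 0.362). PDK4, CPNE9 and C1QC had an adjusted p of 0.504, and NIPAL3 and IPO13 of 0.909. Without NASH 5, 1 gene passed. PDK4 and C1QC were also among the genes of smallest p between NASH and NAFLD, from the same arrays.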

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

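The 6 tests of the macrophage and ribosomal patterns in this part were chosen after their results were seen, and the list tests of the interaction were likewise added after the data were seen. A total of 522 groups, each a measure in a group of arrays, were searched for a single array far from the rest of its group by Dixon's test at the 95% level, over 87 measures. Chance alone marks about 5% of groups, and 34 were marked, so the count as a whole is close to chance. Of these, 6 fell on control 5, 5 on ALD/HCV 6 and 3 each on control 1, HCV 4, NAFLD 2 and ALD 3.

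Control 5 stood apart in its median correlation with the other arrays (0.783), and in the list means of ribosomal proteins (-2.78), oxidative phosphorylation (-1.27), the hypoxia response (-0.82) and fatty acid oxidation (-0.66). METTL15 was also far from the other controls in it, at 2.03. Control 1 stood above the other controls for macrophage markers (1.12), extracellular matrix (1.45) and antigen presentation (0.52). ALD/HCV 6 stood above its group for B and plasma cells (0.79), extracellular matrix (1.00), the interferon response (0.21), antigen presentation (0.90) and MCM3AP (5.89).

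ALD 5 lay apart in the list means of the thick ascending limb (0.95) and the collecting duct (0.56), ALD 4 in skeletal muscle (0.85), NAFLD 4 in adipocyte markers (-0.15), NAFLD 2 in chemokines (0.11), and ALD/HCV 5 in fatty acid oxidation (0.20) and fructose, glucose and urate handling (0.84). HCV 4 lay apart in cell division (0.33), ERRFI1 (5.13) and OR51T1 (1.73), and control 3 in OR8B2 (2.07). VPS26B was far from its group in NAFLD 3 (2.63) and ALD 3 (2.68), CAMP in ALD 3 (1.44), F5 in HCV 3 (2.99) and KRTAP4-2 in NAFLD 2 (3.46). NIPAL3 lay apart in control 2 (4.44) and ALD 3 (4.28), and ALDH3B2 in NAFLD 2 (3.27) and NASH 2 (3.26).

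The interaction of ALD with HCV passed for 5 lists in camera with a preset correlation: podocytes (0.36), macrophages (-0.36), complement (-0.42), cell division (0.17) and ribosomal proteins (-0.56). For macrophages, complement and ribosomal proteins it cannot be told apart from a low control mean beside the disease groups. For cell division and podocytes it cannot be told apart from a high control mean. With an estimated correlation each had an adjusted p of 0.937.

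The ribosomal protein list was 0.70 (SE 0.34) higher in liver disease than in control as a difference of list means. Without control 5 it was 0.33 (SE 0.31), and among arrays numbered 1 to 46 it was 0.32 (SE 0.36), so that control 5, or the class of arrays it belongs to, is a candidate source of much of the difference. Control 5 is itself numbered above 1000, and the design does not separate the array from the class. With the array median as a covariate the difference was 0.80 (SE 0.23). Control was not low in array median (mean 3.27, and 3.19 to 3.31 in the diseases), and the list mean rose with the median. The covariate could therefore hardly have lowered the difference, and other aspects of array quality stay open. A difference between liver diseases and control stays open and was not tested apart from these.

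The macrophage list was 0.43 (SE 0.20) higher in liver disease as a difference of list means. With the array median as a covariate the difference was 0.49 (SE 0.13). Array medians averaged 3.27 in control and from 3.19 to 3.31 in the diseases, and the list mean rose with the median. Control was thus not low in level, and the covariate could hardly have lowered the difference. Other aspects of array quality stay open, as control 5 correlated least at a median of 3.14. Without control 5 the difference was 0.38 (SE 0.22), and among arrays numbered 1 to 46 it was 0.31 (SE 0.25). Both kept the greater part of the difference but lay within 2 SE of 0, so neither the array nor the class can be excluded. More macrophages in the kidneys of patients with liver disease may account for the pattern as well, and no count of cells was analysed here.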

How the results depend on the processing

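Settings chosen only after the data were seen were leaving out control 5, leaving out the 3 least correlated arrays, and the array median as a covariate. No paired analysis was possible because the replicate numbers only name arrays in the order of the series, each biopsy came from a different patient, and the groups share no replicate numbers that the labels tie together. Over settings other than leaving out an array, 1014 of 1243 list results kept their side of the threshold, 220 were no longer called, and 7 became called. The other 2, both of the ribosomal list in NAFLD, lost the call and changed direction, without the arrays numbered above 1000 and with the file number as a covariate (values below). Of 2051 results of named genes, 2036 kept their side and 15 became called. Whatever the side of the threshold, the direction changed in 52 of these list results and 6 of these gene results. When an array was left out, 1882 of 2079 list results and 4478 of 4484 gene results kept their side of the threshold, and the direction changed in 63 and 2. All 370 list mean results stayed short of the threshold, which a lone list could not have passed, and 43 changed direction. The cause of a change was not tested except where the setting itself removes arrays or genes.

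With a correlation estimated from the data, and with fry, 0 lists passed in each of the 9 contrasts where camera with a preset correlation called any. Estimated correlations reached 0.818 for ribosomal proteins and 0.414 for macrophages, far above the preset 0.01.

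With genes below the 30th percentile removed, 0 lists passed in NAFLD, 3 in NASH, 2 in HCV and 3 in ALD/HCV, each against control, and 1 in ALD/HCV against ALD. After quantile normalization 1 gene (A2M) passed in liver disease and 1 (A2M) in NASH. With array medians equalised, 1 gene (A2M) passed in NASH, and lists numbered 0 in NAFLD, 8 in HCV and 8 in NASH against NAFLD. With array weights 1 gene (A2M) passed in NASH, and lists numbered 0 in NAFLD and 10 in ALD/HCV. With podocyte and collecting duct means as covariates, which take away the differences of those 2 lists by construction, 1 gene (A2M) passed in liver disease and 1 (A2M) in NASH, and lists numbered 0 in NAFLD, 7 in HCV, 3 in NASH against NAFLD, 4 between metabolic and other diseases and 8 for the interaction.

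Without arrays numbered above 1000, lists numbered 3 in liver disease, 1 in NAFLD, 2 in NASH, 9 in ALD/HCV, 9 in NASH against NAFLD and 1 for the interaction, and the ribosomal list in NAFLD turned from 0.37 to -0.21 (adjusted p = 0.641). With that class as a term, lists numbered 3 in NASH and 9 in ALD/HCV. With the file number as a covariate among arrays 1 to 46, they numbered 2 in liver disease, 1 in NAFLD, 2 in NASH, 8 in HCV, 9 in ALD/HCV, 8 in NASH against NAFLD and 1 for the interaction, and the ribosomal list in NAFLD was -0.13 (adjusted p = 0.884).

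Without control 5, lists numbered 0 in NAFLD and 1 for the interaction. Without the 3 least correlated arrays 2 genes, PDK4 among them, passed in NASH against NAFLD, and lists numbered 0 in NAFLD and 1 in ALD/HCV against ALD. With the array median as a covariate, genes numbered 6 in liver disease, 1 in NASH, 2 in ALD, 1 in HCV, 50 in ALD/HCV, 1 in NASH against NAFLD and 1 in the F test, and lists 1 in NAFLD, 8 in ALD/HCV and 3 in ALD/HCV against HCV.

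With each array left out in turn, passing lists ranged from 4 to 8 in liver disease, 0 to 2 in NAFLD, 4 to 10 in NASH, 2 to 11 in ALD, 3 to 8 in HCV, 2 to 8 in ALD/HCV, 2 to 12 in NASH against NAFLD, 0 to 1 in ALD/HCV against ALD, 5 to 10 between metabolic and other diseases and 0 to 7 for the interaction. Genes ranged from 0 to 1 in NAFLD, 0 to 1 in NASH, 0 to 3 in NASH against NAFLD and 0 to 1 in the F test. In NAFLD 0 lists passed without control 5 or NAFLD 1, 2 or 5, and 1 without control 1, 3, 4 or 6 or NAFLD 3 or 6. By camera with a preset correlation, the macrophage call held with each array left out in liver disease, NASH, ALD, HCV and ALD/HCV against control and in NASH against NAFLD. Every rerun shared that preset correlation, so the reruns do not test it. With an estimated correlation the list passed in none of these contrasts. The number of arrays limits precision, and 56.3% of genes lay below the 95th percentile of olfactory receptor genes, where differences are hard to measure.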

Other observations

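The glucocorticoid test was written down before its result was seen, as were the counts over other splits; the array median as a covariate, the correlation of list means with it and the splits under it were chosen after the data were seen. With the array median as a covariate, limma passed 50 genes in ALD/HCV against control, 49 higher and 1 (INSL6) lower. Genes are named here after their values were seen, and no list test was run on the 50. Among them were HLA-DMA (1.45, SE 0.26), CD74 (1.31, SE 0.27), the leukocyte genes PTPRC (2.00, SE 0.44) and CD53 (1.58, SE 0.34), JCHAIN (2.53, SE 0.54), and the interferon-related genes IFI16 (1.51, SE 0.30), IRF1 (0.94, SE 0.19) and PARP14 (1.38, SE 0.30). BGN, a matrix proteoglycan, was 1.57 higher (SE 0.33), CST3, which encodes cystatin C, 1.19 (SE 0.23) and A2M 2.23 (SE 0.29). A2M passed as well in liver disease, NASH, ALD, HCV and NASH against NAFLD, and MDK in ALD (1.14, SE 0.21). The 50 also held genes of ribosomal proteins and translation: RPS18 (1.41, SE 0.32), RPL12 (1.32, SE 0.28), RPS15A (1.62, SE 0.36), RPL21, RPL35 and EIF2S3. In NAFLD against control 0 genes passed with this covariate and 0 without it (955 at an unadjusted p under 0.05 and 606 by the exact Wilcoxon test, both without it).

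With the covariate taken as given, 1 of 100 splits of the arrays, the real one, gave as many genes in ALD/HCV (50, highest other 30), and 2 of 100 in liver disease (6, highest other 11). Within that choice few splits reached the real count, though in liver disease another split gave 11 genes. The 2 contrasts split were those with the most genes passing under the covariate, and no other contrast was split under it. The splits allow neither for that nor for the picking of the covariate, so they do not exclude chance. The covariate was picked after its relation to the first component was seen, and a disease could itself move the array median, so the counts are a hypothesis for other samples.

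Without the covariate, chance was not excluded for any count of genes at an unadjusted p under 0.05. Of 100 splits, 10 gave as many as liver disease (1280, highest other 2590), 47 as NAFLD (955, 1859), 22 as NASH (1020, 1712), 39 as ALD (1034, 2874), 16 as HCV (1220, 2853) and 11 as ALD/HCV (1135, 1750). It was 5 for NASH against NAFLD (1331, 1371), 93 for ALD/HCV against ALD (502, 2412), 44 for ALD/HCV against HCV (500, 2868), 57 for metabolic against other diseases (650, 2756), 76 for the interaction (548, 3532) and 32 for the F test (811, 2301). For ALD/HCV against ALD or HCV, the metabolic contrast and the interaction, a split gave several times the real count. This points to a structure of the samples, though no test run here set it apart from genes that vary together by chance.

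Nor was chance excluded for the number of lists passing camera. Of 100 splits, 15 gave as many lists as liver disease (6, highest other 14), 65 as NAFLD (2, 12), 45 as NASH (6, 13), 15 as ALD (7, 14), 50 as HCV (4, 12) and 32 as ALD/HCV (5, 15). It was 19 for NASH against NAFLD (5, 10), 6 for metabolic against other diseases (9, 13) and 27 for the interaction (5, 13), and 100 for ALD/HCV against ALD (0, 12) and against HCV (0, 10).

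List means followed the array median over the 36 arrays. For ribosomal proteins Pearson's r was 0.666 (permutation p = 2e-05, adjusted 3e-05 over the 2 relations) and Spearman's rho 0.734 (permutation p = 1e-05, the smallest that 100000 resamples can give). It was 0.715 without the 2 arrays farthest from the median, 0.757 with group means removed, 0.734 among arrays numbered 1 to 46 and 0.724 without control 5. For macrophage markers r was 0.618 (permutation p = 3e-05, adjusted 3e-05) and rho 0.518 (permutation p = 0.0013), with 0.597, 0.776, 0.604 and 0.608 in the same 4 settings. Arrays numbered above 1000 differed from the others, with group in the model, in 8 genes: BORCS7, C11orf40, FANCM and ANKRD39 higher, WSB1, ST20, ADGRF5 and ACSM2B lower.

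PDK4, ERRFI1, FKBP5 (1.07), TSC22D3 (0.87) and MT1M (0.58) were seen to be higher in NASH than in NAFLD, and all are induced by glucocorticoids. TIMP3 (0.835) and CD163 (2.27) had been seen with them. CD163 is also in the macrophage list, so the macrophage and glucocorticoid patterns share this gene. A glucocorticoid response was put as a hypothesis and tested on 18 other genes of that kind, 17 of them measured. Of these, 4 (DUSP1, SGK1, NFKBIA and ZFP36) were also in lists whose results in this contrast had been seen. MT1X (0.65), MT2A (0.95) and MT1E (0.51) belong to the gene family of MT1M, so the test is not fully independent of the genes seen first. Of the 17, 12 were higher, with a median of 0.51 over all 17, and 4 were lower: ANGPTL4 (-0.57), CEBPD (-0.51), KLF9 (-0.40) and HIF3A (-0.32). FAM107A did not differ (0.00). Of the 8 with an unadjusted p under 0.05 by limma, 7 were higher and ANGPTL4 was lower; 0 passed over all genes and 1 (CRISPLD2, 0.76) adjusted over the list alone. The list mean was 0.24 (SD 0.39) in NASH, -0.10 (SD 0.14) in NAFLD and -0.03 (SD 0.30) in control. It was also high in HCV (0.15, SD 0.38), and was -0.11 (SD 0.21) in ALD and -0.11 (SD 0.19) in ALD/HCV, so it was not particular to NASH. The exact permutation p of the difference in list means, 0.34 (SE 0.17), was 0.0909 over 462 splits, which leaves the hypothesis open (camera p = 0.00813, and p = 0.151 with an estimated correlation). Among arrays numbered 1 to 46 the difference was 0.43 (SE 0.21), which argues against that class as its source, and with the array median as a covariate it was 0.26 (SE 0.14), which cannot be told apart from an effect of array level. Treatment of the patients is not given in the sources used here, and a glucocorticoid effect remains a hypothesis.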
